A study of Mus musculus with 18 samples.

How the data were processed

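Tail DNA of 9 mice was measured against 1 reference male on 18 2-colour Agilent CGH tiling arrays, 2 per mouse with the dyes exchanged. Groups were taken from the labels: 1 sire, 1 dam and 7 progeny. The labels give no sex for the progeny, and none was assigned. The labels name the reference animal by different numbers in the titles and the source names, and it was treated as a single animal. DNA was labelled after version 4.0.8 of the manufacturer's CGH protocol, per the labels. Scans were processed with Agilent Feature Extraction 12.1.0.3, and the probes were placed on mm9, per the file headers.

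The deposited scanner files give an intensity per spot and channel, background-subtracted and dye-normalized with linear factors per the file headers, and a log10 ratio of red over green. The deposited value table holds log2 ratios whose scale and direction were found by setting each column against that array's scanner ratio. The size of r was 0.970 to 0.999 and the size of the slope 0.936 to 0.999, with the reference over the mouse in every column. Column medians ran from -0.009 to 0.014, and the small further step behind these values stays unknown. All columns of the table were used through their sample names.

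Here, log2 of red over green processed signal was turned to mouse over reference. Control spots and outlier-flagged spots were left out, spots of a probe were averaged, and each array was centred on the median of its autosomal probes, with no loess or quantile step. There were 107318 spots per array, 103246 distinct probes, 103195 of them autosomal, 48 on X and 3 on Y. A total of 1026 probes had more than 1 spot. Of the distinct probes, 102923 were well above background in both channels on all arrays, and no spot was saturated. Probes formed 3558 blocks of at least 5 probes, with a median of 28 probes and a median length of 3875 bp, and 32.5% of neighbouring probes overlapped, so they are not independent.

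Segments were called in each mouse with an interval score, the sum of log2 ratios over sigma times the root of the number of probes. Sigma was the robust spread of adjacent probes. A segment needed a score of at least 6, at least 5 probes without a gap over 20 kb, an absolute mean of at least 0.3, and at least 0.2 with the same sign in each orientation. Segments of the same sign that shared at least 0.5 of the shorter were merged into regions. Regions were named by rank of the absolute mean over the mice called: at most 10 in all mice, 10 in a parent and progeny, 10 in progeny only and 5 in parents only. Shares of progeny carry exact 95% Clopper-Pearson intervals. Probes and block means were tested with limma 3.58.1 in R 4.3.3 on 1 value per mouse, with a Benjamini-Hochberg threshold of 0.05. These rules were fixed before the data were examined. The other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

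The caller was tested on simulated data with independent noise at 103195 probes. It recovered 78.6% of implanted segments of 0.3, 99.8% of 0.5 and 100% of 1, with 0 false segments. At 0.3 the share per mouse ran from 43.3% in progeny 6 to 91.0% in progeny 5. Independent noise leaves out waves along the genome. For the test against the reference, simulated on 103088 probes, 83.6% of probes changed by 0.3 were recovered. For blocks in 1 mouse, simulated on 3558 blocks in 9 mice, it was 94.0%.

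The files pair no probe with a gene, and the annotation given was of another build, so the gene lists and gene names planned before the data were examined were not analysed here, and regions are given by position alone. The scanner files hold no mean signals, so normexp, with an offset of 50, was run on median signals. Alternatives covered normexp, the value table, dim probes, loess (span 0.3), a probe baseline, the caller's thresholds, single dye orientations, slides as a random block and leaving out each mouse.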

Results

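Genomic DNA from the tails of 1 mouse family, a sire, a dam and their 7 progeny, was compared with DNA of 1 reference male of the same colony on 18 tiling arrays. The strain was C57BL/6JNrs, an inbred mouse strain. Each mouse was hybridised on 2 arrays with the dyes exchanged, and both orientations were averaged, so that 1 mouse gave 1 value per probe. The series asks whether gamma rays given to males at 0.05 mGy per day for 400 days leave copy number changes in their offspring. Its title counts this family among those of exposed males, while its design text calls the sire non-irradiated, so the exposure of this sire is not settled here. The array carried 103195 autosomal probes, placed around candidates from an earlier genome-wide screen of the same family. Its regions are therefore no random sample of the genome and no independent evidence of change. Median signal over background ranged from 26.5 to 39.3 in the green channel and from 28.5 to 41.8 in the red channel, and the number of arrays limits the precision. Positions are on mm9, and no gene was assigned to a region. All log2 ratios are mouse over reference, and errors of single mice are the SD of their 2 arrays.

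The X chromosome probes set the direction and scale of the ratios. The median of 48 X probes was 0.93 ± 0.04 (SD, n = 2 arrays) in the dam and -0.01 ± 0.05 (SD, n = 2 arrays) in the sire, against a male reference. The median of 3 Y probes was 0.01 ± 0.13 in the sire and -3.42 ± 0.47 in the dam. Only 1 of the 3 Y probes was well above background on all arrays, and the size of the dam's value rests on the treatment of background: it was -0.91 with normexp and -0.62 on the probe well above background.

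The first comparison set the whole family against the reference male. Of 1130 merged regions, 4 were called with the same sign in all 9 mice, 1 gain and 3 losses. The gain spanned 161574 bp of chromosome 4, from 101109394 to 101270967, and held 982 probes. It lay at 0.51 ± 0.05 in the sire and 0.90 ± 0.05 in the dam. Among the progeny it was 0.51 ± 0.07 in progeny 1, 0.51 ± 0.04 in progeny 5 and 0.50 ± 0.05 in progeny 6. It was 0.85 ± 0.04 in progeny 2, 0.92 ± 0.05 in progeny 3, 0.93 ± 0.05 in progeny 4 and 0.93 ± 0.05 in progeny 7. The gap between these levels exceeded the spread between dye orientations. The 3 losses lay close together on chromosome 14. From 53712663 to 53720819 the ratios ran from -0.89 in progeny 7 to -0.77 in progeny 1. From 53758406 to 53759816 they ran from -0.94 in progeny 1 to -0.70 in progeny 6. From 53966207 to 53992612 they were smaller, from -0.31 in progeny 5 to -0.16 in progeny 6 over the whole region. A pair of neighbouring losses, from 54290185 to 54298759 and from 54382603 to 54386879, chosen after their values were seen, were each called in 8 of the 9 mice. Whether these losses lie in antigen receptor loci, which are rearranged in lymphocytes, was not analysed here. Because every array shared the reference, these regions mark a difference between that animal and the family without showing which side changed. The levels of the chromosome 4 gain also differed between mice of the family, which a shared reference cannot produce.

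**Figure D1:**
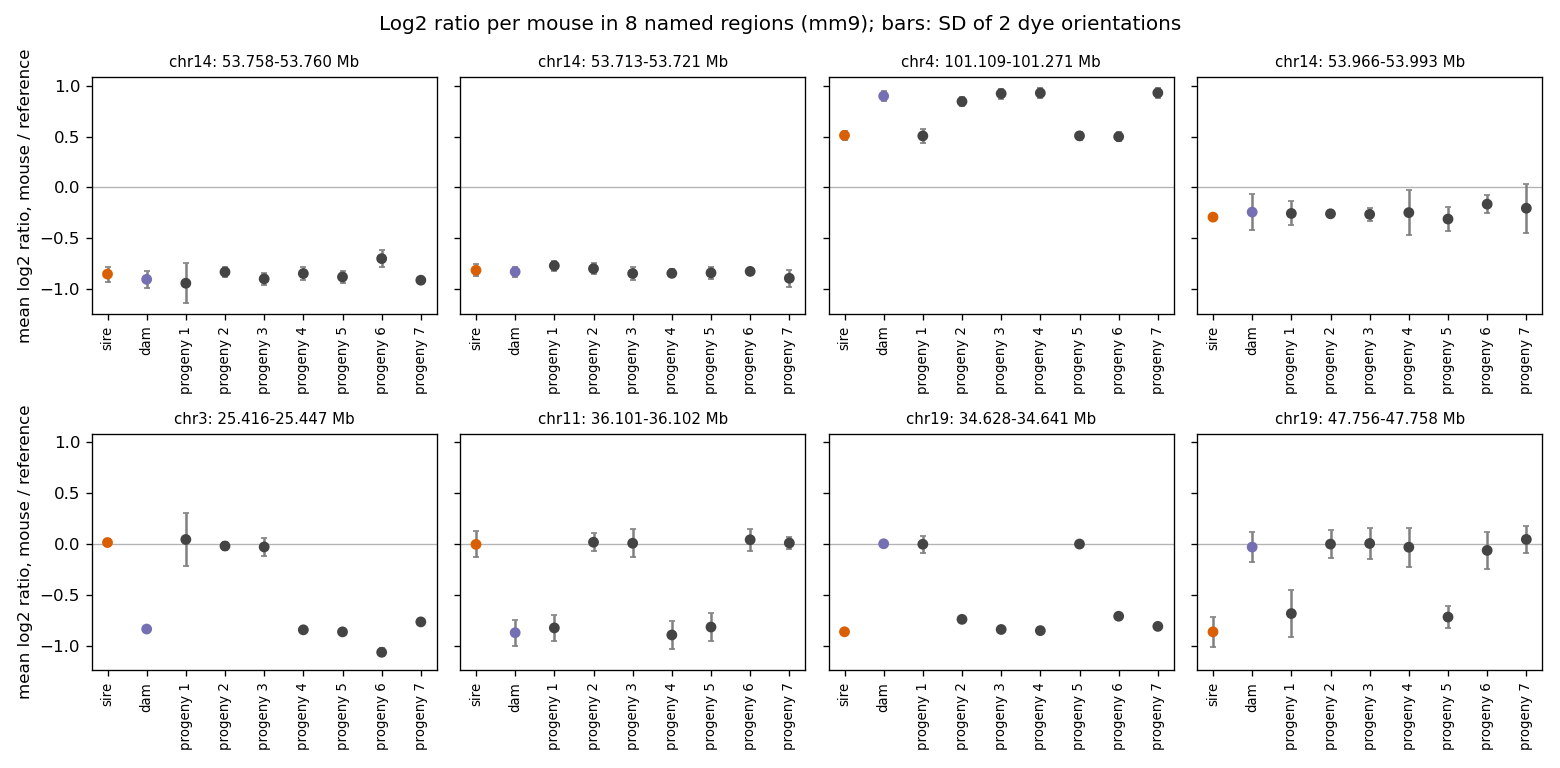
Mean log2 ratio of mouse over reference (vertical axis) for the sire (orange), the dam (purple) and the 7 progeny (grey) in the 4 regions called in all mice and the 4 named losses called in a parent and progeny. Bars are the SD of 2 dye orientations, and on chromosome 4 the mice lie near 0.51 or between 0.85 and 0.93.

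Probe by probe, limma with Benjamini-Hochberg adjustment over 103195 autosomal probes found 3618 that differed from the reference, 3112 higher and 506 lower (9 mice). Of these, 1598 differed by at least 0.3, with 1474 higher and 124 lower. The chromosome 4 block held 973 of the 1598 probes, all higher, or 60.9%. A block on chromosome 19 from 34626858 to 34643334 held 64, all lower, and the chromosome 14 block from 53712663 held 15, all lower. The loss within the chromosome 19 block was not shared by the whole family: the dam, progeny 1 and progeny 5 lay at 0.00. The reference is 1 animal, so its own spread is left out. The count of 3618 was not stable: it was 10862 without progeny 1 and between 1405 and 1822 without the sire, the dam, progeny 3, progeny 4, progeny 5 or progeny 7. Higher probes prevailed without any single mouse, but the split was 10985 higher and 8100 lower without both progeny 1 and progeny 6. It was 17150 and 17240 with the Cy5-labelled mouse alone, and 28972 and 28289 with the Cy3-labelled mouse alone.

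The second comparison asked which changes of a parent were seen in the progeny. A total of 190 regions, 168 gains and 22 losses, were called in a parent and in progeny. Of the 10 ranked highest by mean log2 ratio, 4 were losses. On chromosome 19, from 34628063 to 34641013, the sire lay at -0.86 and the dam at 0.00. The loss was called in 5 of the 7 progeny, 71.4% (95% Clopper-Pearson interval 29.0 to 96.3%), with ratios from -0.85 in progeny 4 to -0.71 in progeny 6, while progeny 1 and 5 lay at 0.00. A second loss of chromosome 19, from 47756239 to 47758365, lay at -0.86 ± 0.15 in the sire and -0.03 ± 0.14 in the dam. It was called in 2 of 7 progeny, 28.6% (3.67 to 71.0%), at -0.68 ± 0.23 in progeny 1 and -0.72 ± 0.11 in progeny 5. On chromosome 11, from 36101013 to 36101829, the dam lay at -0.87 ± 0.13 and the sire at 0.00 ± 0.13. That loss was called in 3 of 7 progeny, 42.9% (9.90 to 81.6%), at -0.83 in progeny 1, -0.90 in progeny 4 and -0.82 in progeny 5. On chromosome 3, from 25415863 to 25447093, the dam lay at -0.84 ± 0.01 and the sire at 0.01 ± 0.03 over the whole region of 13 probes. The segment called in the dam, 7 probes from 25421508 to 25443259, was lower, at -1.35. The mean of the segments called in this region was -1.18. The loss was called in the dam and in 4 of 7 progeny, 57.1% (18.4 to 90.1%). Over the whole region their ratios ran from -1.07 in progeny 6 to -0.77 in progeny 7. The X probes of these same 5 mice were high, from 0.91 to 0.96. Their Y medians, from 3 probes of which only 1 was well above background, ran from -3.90 in progeny 7 to -3.32 in progeny 5. The other mice ran from -0.14 in progeny 1 to 0.01 in the sire. The loss went with these sex chromosome signals, so its share need not reflect an autosomal change passed on.

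The other 6 of the 10 were gains of 374 to 711 bp in both parents and in progeny 4 and 5, 1 of them also called in progeny 6. The gain on chromosome 11 from 45162030 to 45162528 lay at 0.85 in the sire, 0.78 in the dam, 0.84 in progeny 4 and 0.43 in progeny 5. On chromosome 15, from 92612514 to 92613045, the ratios were 0.79, 0.74, 0.88 and 0.37 in these mice. Progeny 6 lay at 0.32 in the chromosome 11 gain and 0.30 in the chromosome 15 gain. It passed the size of 0.3 there but was not called. Progeny 7 lay at -0.19 and -0.14. Regions called in exactly this set of 4 mice numbered 59, on 19 chromosomes. Their median ratios were 0.65 in the sire, 0.64 in progeny 4, 0.56 in the dam, 0.35 in progeny 5 and 0.185 in progeny 6. In the other progeny they ran from -0.15 in progeny 7 to 0.05 in progeny 3, so the set rests in part on the call limits. The count of 190 fell to 110 without progeny 4 and to 98 when a size of at least 0.5 was required.

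The third comparison asked which regions were called in progeny and in neither parent. There were 916 such regions, 658 gains and 258 losses, with a median length of 754.5 bp. Progeny 6 was called in 824 of them, and alone in 702. Progeny 4 was called in 197, progeny 7 in 49, progeny 5 in 12, progeny 3 in 4, progeny 2 in 2 and progeny 1 in 1. All 10 ranked highest were called in progeny 6 alone. The first of them, a gain on chromosome 3 from 43539584 to 43540924, lay at 0.69 ± 0.15 in progeny 6, 0.09 in the sire and 0.12 in the dam. The sixth, on chromosome 3 from 140075566 to 140075954, lay at 0.60 in progeny 6. It overlapped gains called from 140075792 to 140076501 in the sire (0.71), the dam (0.66), progeny 4 (0.72) and progeny 5 (0.39), by too little to be merged with them. In all, 9 of the 916 regions overlapped a call of the same sign in a parent in this way, and with any overlap counted as shared the 916 became 898. With normexp the first of these gains lay at 0.37 in progeny 6 and the sixth at 0.35. In 378 of the 916 regions a parent lay at 0.1 or more on the same side. At a size of 0.5 or more with both parents within 0.1 of 0, a limit chosen after the values were seen, 8 regions were left, all in progeny 6 and at most 1375 bp long. In these 8 both parents lay on the same side as progeny 6, except the sire on chromosome 1 from 166144283, at 0.006. Some lay just inside the limit, such as the dam on chromosome 8 from 30720368, at 0.0995. Without progeny 6 the count of 916 became 216, and with loess per array it became 306.

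**Figure D2:**
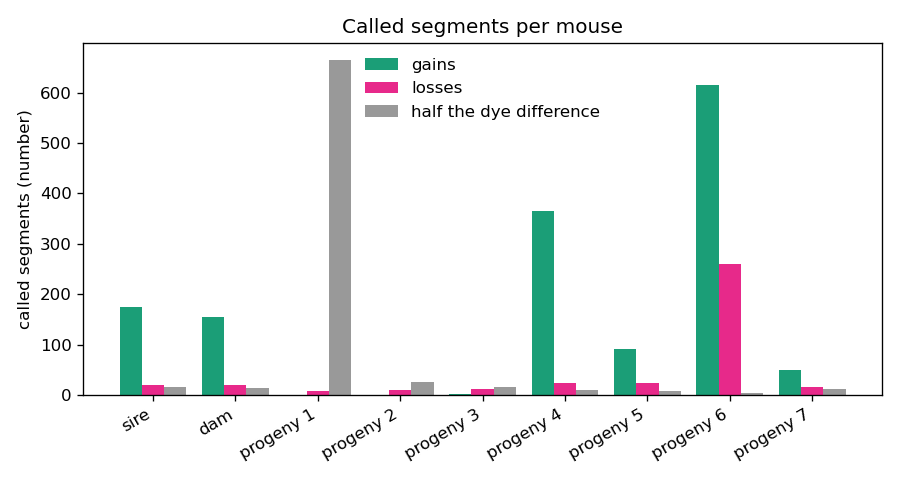
Number of called segments (vertical axis) in each of the 9 mice, as gains, losses and segments called on the difference between dye orientations divided by 2, which holds no copy number. Progeny 6 had 614 gains and 261 losses, and progeny 1 had 665 segments in the dye difference.

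Between generations, limma found 0 of 103195 autosomal probes that differed between the 7 progeny and the 2 parents after Benjamini-Hochberg adjustment, with 2924 at an unadjusted p under 0.05 and a smallest adjusted p of 1. Both parents shared 1 slide that held no progeny. Slide as a random block also gave 0, but its estimated correlation was -0.0037, and it does not separate that slide from the generation. In simulated data of 103088 probes, with noise independent across probes and mice, this test recovered 22.4% of probes changed by 0.3. It recovered 59.7% of those changed by 0.5 and 92.4% of those changed by 1. The real data gave fewer p-values under 0.05 than independent noise gives, so these shares need not hold for the real test.

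Changes private to a mouse were tested on the means of 3558 tiled blocks, each mouse against the other 8. Of 32022 block and mouse pairs, 1 passed the limma test after adjustment. It was a block on chromosome 5 from 18741121 to 18744083, higher by 0.21 in progeny 6 (limma, adjusted p = 0.016). No pair passed with a difference of at least 0.3, while 2149 had an unadjusted p under 0.05. The single mouse adds no spread of its own to this test, and the other 8 supply all of it. The call was lost with loess per array, with normexp, and without progeny 2, progeny 3 or progeny 5, while without progeny 1 the number of passing pairs was 165, of which 0 differed by at least 0.3. A change in part of a block is diluted in its mean.

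Regions called in parents only numbered 20, 11 gains and 9 losses. The largest, a gain on chromosome 1 from 122619745 to 122620340, lay at 0.48 ± 0.01 in the sire and 0.37 ± 0.05 in the dam. It overlapped gains called from 122619337 to 122619974 in the dam (0.39) and progeny 4 (0.44), by too little to be merged with them. Of the 20 regions, 5 overlapped a call of the same sign in progeny in this way. The count was 100 without progeny 4 and 4 without the sire, in which alone 18 of the 20 were called.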

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

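All tests of explanations in this part were chosen after the results were seen. Among the 7 progeny, 5 of 30 values lay far from the others. Chance alone gives such a value in about 1 of 20 independent groups, but these groups are not independent. Most of the 5 describe the same mouse, progeny 6, so these shares cannot be compared. Progeny 6 stood apart with 261 losses against at most 24 in another progeny. It also had a probe SD of 0.275, an adjacent-probe spread of 0.156 and a derivative spread of 0.190 on its Cy3 array. Its ratios of 0.64 on chromosome 8 from 36831215 and 0.61 on chromosome 14 from 17751125 were also far above the rest, but these are 2 of 10 regions named because progeny 6 alone was called in them, so that selection set them apart. Progeny 1 stood apart with 665 segments in its dye difference, against at most 26 in another progeny. X probes of progeny, for which no test was run, lay at 0.96 in progeny 4, 0.91 in progeny 5, 0.94 in progeny 6 and 0.95 in progeny 7, against -0.01 in the sire.

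Most regions called in progeny only lay in progeny 6. Noise of single hybridisations is argued against, since its dye orientations correlated across probes (Pearson r = 0.716). Whether the signal was confined to progeny 6 is not decided by the signs of other mice in the 702 regions called in it alone. All mice shared the reference, so a small offset of the reference would give them the same sign. In the gains the median was 0.39 in progeny 6 and ran from -0.07 in progeny 1 to 0.15 in progeny 4 elsewhere. In the losses it was -0.38 in progeny 6 and ran from -0.10 in progeny 4 to 0.14 in progeny 1. The sign of progeny 6 was seen in 99.4% for the dam, 99.3% for progeny 4, 97.9% for progeny 2 and 96.6% for progeny 3. It was 92.2% for progeny 7, 86.3% for the sire and 67.0% for progeny 5, but 2.14% for progeny 1. Whether progeny 6 changed beyond this shared sign stays open: progeny 4 reached 0.5 of its log2 ratio in 14.8%. A trend with intensity also stays open, since loess per array kept a median of 72.2% of the log2 ratio in these regions and left 267 of the 702 at 0.3 or more. Its 875 called segments became 215 with loess, but also 168 at a score of 8 and 17 with the spread of all probes, neither of which corrects for intensity.

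Short gains called in both parents and in progeny 4 and 5 formed a set of 59 regions. They lay on 19 chromosomes, but the mice called defined the set, so this spread alone does not test independent transmission. The gains over all called segments argue against it. The sire had 174 and the dam 156, while progeny 1 and 2 had 1 each and progeny 3 had 2. A comparison of mice within slides was tried and dropped, since the regions were chosen by the mice called in them. A slide difference alone is argued against by the gains over all called segments. Progeny 3 and 4 shared a slide and had 2 and 366, and progeny 5 and 6 shared another and had 91 and 614. The sire and dam, also on a single slide, were alike with 174 and 156, as were progeny 1 and 2 with 1 each. A part played by slides and a property of the DNA samples stay open.

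Losses called in exactly the dam and progeny 4, 5, 6 and 7 numbered 7, on 6 chromosomes. The mice called defined the set, so this spread alone does not test losses passed on independently. Every other set of mice called for losses in the dam and progeny but not the sire held only 1 loss, which argues against it. Binding of the probes in these 7 losses to Y sequence stays open. A ranking of the mice by the Y median was tried and dropped. The mice called defined the set, and only 1 of the 3 Y probes was well above background on all arrays. Probe sequences were not analysed here.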

How the results depend on the processing

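Leaving out mice from the region counts, leaving out both progeny 1 and progeny 6, the spread over all probes, and the alternatives for the sex chromosomes were chosen after seeing the data. No paired analysis was possible because the sire and dam are single animals. Regions in all mice numbered 3 to 6 under the alternatives that gave a count, which leave out the probe baseline and the dye difference. In the fits run for each, 0 probes differed between generations and 0 blocks reached 0.3, and blocks were not fitted for single orientations or slides. The cause of the changes below was not tested. Called segments (1851), regions in progeny only (916), in a parent and progeny (190) and in parents only (20) became, in that order, 770, 423, 89 and 4 with at least 10 probes, 3385, 1471, 289 and 55 at a size of 0.2, and 465, 130, 98 and 4 at a size of 0.5. The probe baseline gave 990, 580, 110 and 13. Segments and regions in progeny only became 1051 and 269 with normexp, 1097 and 306 with loess, 1144 and 309 at a score of 8, 993 and 220 with the spread of all probes, and 967 and 215 without both progeny 1 and progeny 6. At least 3 probes gave 3032 segments, 1399 regions in progeny only and 36 in parents only. A score of 5 gave 1715 regions in progeny only. Segment counts changed in progeny 6 alone, from 875 to 1726 at a score of 5, 168 at a score of 8 and 17 with the spread of all probes. These settings thus acted on the calls of that mouse only. The Cy5-labelled mouse alone gave 2970 segments, 1617 regions in progeny only and 34 in parents only, and the Cy3-labelled mouse alone 317 in a parent and progeny and 119 in parents only. The dye difference divided by 2 gave 775 segments, 665 of them in progeny 1.

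Leaving out each mouse gave 976 to 1842 called segments, 216 to 937 regions in progeny only, 110 to 190 in a parent and progeny and 4 to 100 in parents only. Segments were called in each mouse alone, so leaving out a mouse removes only its own segments. The range of called segments therefore shows how many each mouse held and does not test the calls. Probes against the reference (3618) ranged from 1405 to 10862, and blocks in 1 mouse (1) from 0 to 165, the highest without progeny 1. Probes against the reference numbered 5769 with normexp, 19085 without both progeny 1 and progeny 6, 34390 with the Cy5-labelled mouse alone and 57261 with the Cy3-labelled mouse alone. At 0.3 or more these orientations gave 3241 and 5451. Blocks in 1 mouse were 0 with normexp, with loess, and without both progeny 1 and progeny 6. The dam X median was 1.01 with normexp, the dam Y median -0.91 with normexp and -0.62 on probes well above background, and the sire Y median 0.17 with the Cy3-labelled mouse alone. No named region changed sign, but 53 of 199 values of named regions moved by more than their spread, and 19 of the 199 changed by over 1.5 times, 9 with the probe baseline and 6 with normexp. The probe baseline, a median over all mice, removes changes that most mice share: the chromosome 19 loss from 34628063 came to -0.07 and the chromosome 3 loss from 25415863 to -0.15. The chromosome 14 loss from 53966207, at -0.25, became -0.14 with normexp, -0.30 with loess and -0.39 on probes well above background. Signal over background limits the Y probes.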

Other observations

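The hypotheses and tests in this part were chosen after the values were seen. The chromosome 4 gain may reflect 3 copies in some mice and 4 in others against 2 in the reference. Scaled by the X median of the dam, those copy numbers predict 0.54 and 0.93. Every one of the 9 mice lay within 0.1 of one of them, with a largest distance of 0.084. With the dam near the higher level and the sire near the lower, no progeny lay near the level of the reference. A reference with fewer copies was not tested.

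The chromosome 19 losses of the sire, 13.1 Mb apart, may lie on opposite homologues. Each of the 7 progeny was called for exactly 1 of them, 7 of 7. An exact two-sided binomial test against unlinked losses gave p = 0.0156, without adjustment for the choice of this pair. Both losses lie on 1 chromosome, so that null is in doubt from position alone. The test counts both directions, so by itself it does not set opposite homologues against the same homologue. Losses on the same homologue would be passed on together, except after recombination between them. All 7 progeny were called for exactly 1, which argues against the same homologue for this pair.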
